A study of Rattus norvegicus with 8 samples.

How the data were processed

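RNA from rat PC12 cells was measured on 8 microarrays. The labels sort the arrays by chip (A or B) and by treatment (forskolin or no forskolin), which gives 4 groups of 2 arrays, numbered replicate 1 and replicate 2. The values analysed are the authors' processed log2 expression values, 1 per probe set and array, as deposited in a table for each chip. How the authors computed them (background correction, summary of the probes, scaling) is not given in the sources used here. The log base was inferred from the deposited values: raised to base 2, 100% of them lie within the range of a 16-bit scanner, whereas 3063 values on chip A and 115 on chip B would exceed it if they were natural logarithms. No detection calls were used here, and the tables held 0 control probe sets, so neither background nor hybridization controls could be checked.

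The 2 tables were made separately and were analysed separately, because levels that were scaled separately are not on 1 scale. A level was set across the chips only in a check of brightness, through the probe sets that both chips carry. The array medians differed by at most 0.021 on chip A and 0.025 on chip B (log2). A rule fixed before the data were examined keeps the authors' scaling where the medians lie within 0.1 of each other, so no further normalization was applied. The values were already logarithms and no pseudocount was added. Probe sets whose mean linear value over the 4 arrays lay under the 30th percentile of the chip were left out, which kept 11106 of 15866 probe sets on chip A and 10693 of 15276 on chip B.

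Gene names came from the annotation of the 2 chips at GEO, with symbols updated through the Entrez gene number to the current RefSeq gene table of rat (assembly GRCr8). Of the probe sets on chip A, 12783 carried 1 gene symbol, 312 carried several and 2771 carried none. The same numbers on chip B were 7564, 100 and 7612. By gene number, 12748 probe sets on chip A and 7524 on chip B matched the RefSeq table. Probe sets with several symbols or none were tested but are not named. No genome sequence was used and no coordinates are given.

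Forskolin was compared with no forskolin on each chip with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets of the chip. Adjusted p under 0.05 was the threshold for a call. Rose and fell are used for calls, and every log2 change is forskolin minus no forskolin, with the moderated standard error (SE) of limma and n = 2 arrays per group. The standard error of a log2 change had a median of 0.045 on chip A and 0.089 on chip B, which corresponds to a median 95% half-width of 0.10 and 0.21. The number of arrays limits this precision.

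Before the data were examined, 21 gene lists were fixed. They cover immediate early transcription factors, cyclic AMP signalling, MAP kinase phosphatases and Sprouty proteins, catecholamine synthesis, neuropeptides and granins, exocytosis, neurite growth, voltage-gated channels and nicotinic receptors, the circadian clock, the cell cycle, cell cycle inhibitors, sterol synthesis, the unfolded protein and amino acid stress response, heat shock proteins, glucose metabolism and hypoxia, oxidative phosphorylation, ribosomal proteins, and markers of fibroblasts, glia, adrenal cortex, and blood and endothelium. A gene entered the count of its list through its brightest tested probe set, on chip A where it was tested there and otherwise on chip B. Each count is also given adjusted over the list alone. Lists with at least 5 tested genes on a chip (18 on chip A and 5 on chip B) were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of the chip. Camera with an estimated correlation and limma's fry were run beside it. At the preset correlation, camera compares the genes of a list with the other genes. Its p-values then rest on the number of genes and can be very small with few arrays. With an estimated correlation, camera's p-values also rest on the few arrays of a chip. A call lost that way does not by itself point to correlation between genes.

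The genes named were set by a rule written before the data were examined. It takes calls with 1 gene symbol whose groups do not overlap, each gene through its probe set with the smallest p, and names the 15 genes with the largest rise and the 10 with the largest fall on chip A, and up to 5 of each on chip B, filled up to 10 with the smallest p-values. It adds the 4 members of each list with the smallest p, and a fixed panel of genes known to respond to cyclic AMP or to mark PC12 cells, with Actb and Gapdh as technical checks. No probe set that carried only the symbol Actb or only Gapdh was found, so that check was not made. Genes named outside the rule are said to have been chosen after their values were seen.

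The tests were tried on simulated data with 200 changed probe sets, in 10 simulations per chip that drew variances from limma's fitted prior. With the 11106 probe sets of chip A, 89% of 1.25-fold changes and 99.2% of 1.5-fold changes were recovered, with 4.39% false calls. With the 10693 probe sets of chip B, 5.4% of 1.25-fold, 68.8% of 1.5-fold and 99% of 2-fold changes were recovered, with 4.35% false calls. The noise followed the model that limma assumes and held no factor shared by same-numbered arrays. These shares hold under that model only, and the false-call shares do not measure how often calls in the data are false. In 20 simulations on the 8007 genes of chip A, camera called a list of 17 genes shifted by 0.1 (log2) in 100% of runs and unshifted lists in 1.47% of tests. Noise was drawn independently for each probe set, so the genes of a list were uncorrelated. In the data the estimated correlation within a list on chip A reached 0.28, for neurite growth. The 1.47% may therefore understate false calls among the real lists.

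The alternatives were quantile normalization, median centring, pseudocounts at the 2nd and 25th percentiles, no filter and a filter at the 50th percentile, eBayes without a trend and with robust variances, the replicate number as a block, each array left out in turn, another threshold and a minimum fold, and for the lists an estimated correlation, the probe set with the smallest p, and fry. A further alternative, chosen after seeing the data, left out of every other list the genes that the immediate early list also holds.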

Results

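Expression was measured in PC12, a line grown from a tumour of the rat adrenal medulla whose cells make and store catecholamines. Forskolin is a plant diterpene that activates adenylyl cyclase, the enzyme that makes cyclic AMP. The series title sets it against an inactive control, and the labels of the control arrays say only that they had no forskolin. The dose, the time of exposure and the nature of the control are not given in the sources used here. Total RNA was measured on 2 chips, A with 15866 probe sets and B with 15276, of which 100 are on both. Each chip had 2 forskolin arrays and 2 arrays without forskolin. The array medians lay between 8.15 and 8.17 (log2) on chip A and between 6.77 and 6.79 on chip B. The labels do not say that replicates came from separate cultures, so limma's p-values for probe sets measure only the spread between these samples, which may be technical. The p-values of camera at the preset correlation rest on the spread across genes and do not measure variation between samples. Arrays of the same group on chip A correlated across probe sets at r = 0.9984 to 0.9985, and arrays of different groups at 0.992 to 0.993. On chip B the ranges overlapped, with 0.986 to 0.992 within groups and 0.987 to 0.990 between them. Probe sets are not independent replicates.

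The comparison asks which transcripts differ in abundance between PC12 cells with and without forskolin. The 6 genes with the largest rises on chip A were Fos, Nr4a3, Dusp1, Nr4a1, Sik1 and Nr4a2. Fos, a subunit of the AP-1 transcription factor, rose from 5.22 ± 0.11 to 9.25 ± 0.12 (log2, SD, n = 2), a 16.4-fold rise. The 3 NR4A orphan nuclear receptors rose together, Nr4a3 by 3.53 ± 0.10 (log2, SE), Nr4a1 by 2.77 ± 0.07 and Nr4a2 by 1.98 ± 0.06. Without forskolin, Fos, Nr4a3 (5.88) and Nr4a2 (6.02) lay below the lowest mean level that the filter kept on chip A (7.02). They passed it through their forskolin arrays. How far such levels lie above background is not known, so the sizes of these rises are uncertain. Dusp1, a phosphatase that switches off MAP kinases, rose 9.48-fold, and Sik1, a kinase that restrains the CREB coactivators, rose 5.94-fold. Txnip, an inhibitor of thioredoxin and of glucose uptake, fell from 11.37 ± 0.05 to 9.87 ± 0.02 (log2, SD, n = 2).

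Among 11106 tested probe sets on chip A, limma called 226 higher and 140 lower at adjusted p under 0.05, or 3.30%. They carried the symbols of 165 genes that rose and 120 that fell. The rises were larger, with a median of 1.34-fold against 1.20-fold for the falls, and 36 rises but only 3 falls reached 2-fold. At an unadjusted p under 0.05, 788 probe sets were higher and 1146 lower. The 2 groups did not overlap in 48.5% of tested probe sets, where chance gives 33.3%. Without forskolin replicate 1 the count of lower probe sets was 83, and without forskolin replicate 2 it was 85. Median centring of the arrays gave 300 higher and 277 lower.

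**Figure D1:**
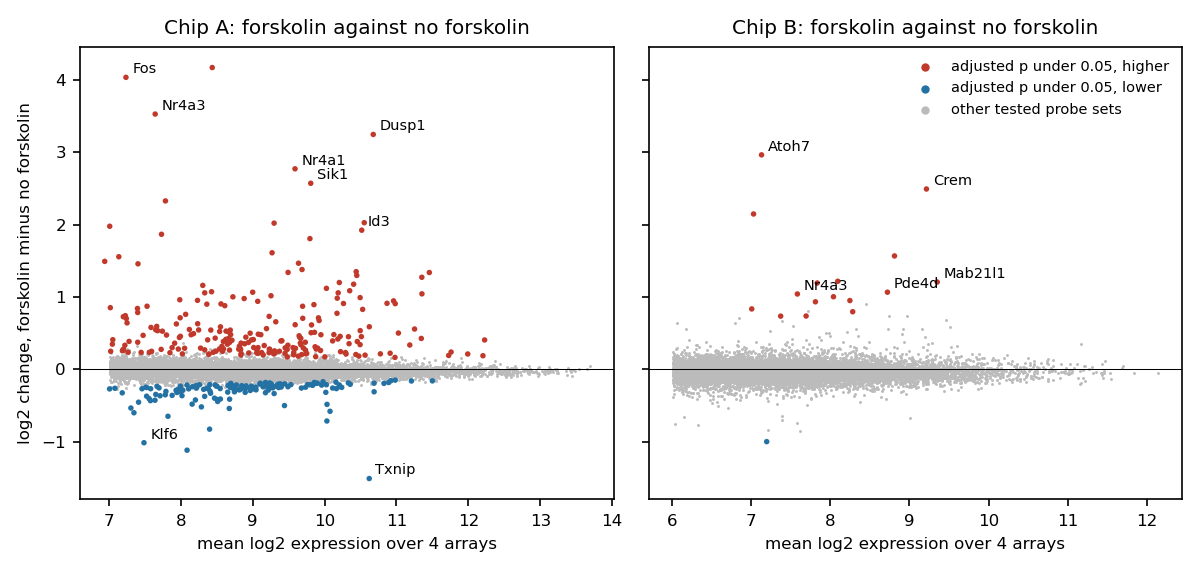
Log2 change (forskolin minus no forskolin) against mean log2 expression over the 4 arrays of chip A (left) and chip B (right), with 1 point per tested probe set, red for calls that were higher, blue for calls that were lower and grey for the rest. Chip A holds 226 red and 140 blue points, chip B 16 and 1, and the named points give a gene's probe set with the smallest p.

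The other genes among the 15 largest rises on chip A span transcription, signalling and metabolism. Id3, an inhibitor of basic helix-loop-helix factors, rose 3.79-fold, and the transcription factors Klf4, Junb and Gata2 rose 3.50-fold, 3.05-fold and 2.55-fold. The bradykinin B2 receptor gene Bdkrb2 rose 2.94-fold, the stress-response gene Ier3 2.76-fold, and Rgs2, which shortens G protein signalling, 2.75-fold. Bdkrb2 (6.36) and Rgs2 (6.68) also lay below the level of the filter (7.02) without forskolin. Coq10b, which serves coenzyme Q function in mitochondria, rose 2.60-fold, and Rhou 2.53-fold. The largest limma adjusted p among these 15 genes was 8.72e-06, for Bdkrb2, and both forskolin arrays lay above both control arrays for each of them. Further probe sets of Dusp1, Nr4a2, Sik1 and Rgs2 on chip A rose by 4.17, 2.33, 1.87 and 1.49 (log2), while that of Nr4a3 rose by only 0.53 and those of Bdkrb2 by 0.96 and 0.74.

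The falls were fewer in number and smaller. After Txnip, the largest were in Klf6, a zinc finger transcription factor, by 1.01 ± 0.07 (log2, SE, n = 2), and Pik3ip1, an inhibitor of PI 3-kinase, by 0.71 ± 0.05. Gadd45a and Gadd45g, stress sensors linked to growth arrest, fell 1.57-fold and 1.45-fold. Rsrp1 fell 1.41-fold on chip A, with -0.39 (log2, not called) on chip B, Filip1l 1.40-fold, the kinase gene Sgk1 1.39-fold, and Lcat, which esterifies cholesterol in plasma lipoproteins, 1.37-fold. LOC100912167, named only by its locus number, fell 1.43-fold. The limma adjusted p of these 10 genes lay between 1.07e-07 for Txnip and 0.00608 for Gadd45g.

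**Figure D2:**
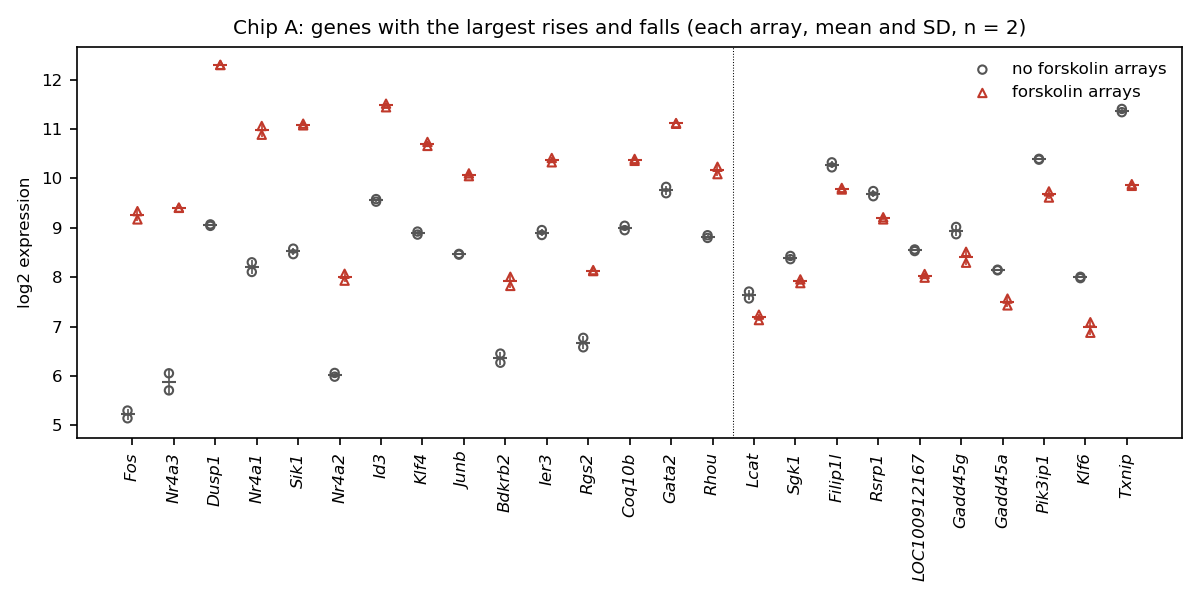
Log2 expression on the 4 arrays of chip A for the 15 genes with the largest rises and the 10 with the largest falls, divided by a dotted line, with circles for arrays without forskolin, triangles for forskolin arrays, and horizontal and vertical bars for the group mean and SD (n = 2). The forskolin arrays lie above the others for every gene from Fos to Rhou and below them for every gene from Lcat to Txnip.

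Of 28 tested immediate early transcription factors and related genes, 20 rose, 1 fell and 7 were not called; adjusted over the list alone, 21 rose and 2 fell. The growth-response factor Egr1 rose 2.23-fold, Per1 1.63-fold and Crem, which encodes activators and repressors of cyclic AMP-responsive genes, 1.84-fold on chip A. Klf6 was the member that fell. Jun, chosen after its values were seen, was not called on its brightest probe set (-0.13), while its other 2 probe sets fell by 0.36 and 0.27 (log2). A second Fos probe set measured 0.06 (adjusted p = 0.519, limma) with a level of 7.86 without forskolin, so the Fos result rests on 1 of 2 tested probe sets. Fosb lay below the brightness filter and was not tested; its log2 difference was 0.77. Limma's camera called the list higher (adjusted p = 1.88e-31), a call not held at adjusted p = 0.0998 with an estimated correlation.

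Of 29 tested genes of cyclic AMP signalling and feedback, 5 rose and none fell; adjusted over the list alone, 6 rose. They were Sik1, Rgs2, Crem, the cyclic AMP phosphodiesterase gene Pde4d (1.94-fold) and, chosen after its values were seen, its relative Pde4b (1.72-fold). Phosphodiesterases of this family break down cyclic AMP. The other 24 members were not called by limma on their brightest probe sets, and the median of the list was 0.04 (log2). Rgs4, named after its values were seen, was called lower on 1 of its 2 tested probe sets, which measured -0.16 and -0.09. Camera called the list higher (adjusted p = 9.81e-04), but adjusted p = 0.342 with an estimated correlation. Of 10 MAP kinase phosphatases and Sprouty proteins, Dusp1 and Dusp5 (2.00-fold) rose and none fell; adjusted over the list alone, 3 rose. Dusp4 measured 0.20 (limma adjusted p = 0.0744, but 0.0489 by eBayes without a trend) and Dusp10, on chip B, -0.16 (0.977). Camera, run on the 6 of these genes tested on chip A, called this list higher (adjusted p = 1.64e-05), with adjusted p = 0.342 with an estimated correlation.

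Of 9 genes of catecholamine synthesis, storage and uptake, 1 rose and 1 fell; adjusted over the list alone, 2 rose and 1 fell. Both called genes belong to the pathway that makes tetrahydrobiopterin, the cofactor of tyrosine hydroxylase: Gch1, its first enzyme, rose 1.58-fold (1.27-fold on its other probe set) and Pts, a later one, fell 1.32-fold. Tyrosine hydroxylase itself (Th), the rate-limiting enzyme of catecholamine synthesis, was not called over all probe sets. It measured 0.11 with a 95% interval of 0.03 to 0.19 (log2, limma adjusted p = 0.153). Adjusted over the list alone, Th was the other gene that rose. Maoa measured -0.07. Camera did not call the list (adjusted p = 0.444). None of 16 tested neuropeptides, granins and processing enzymes was called by limma, over all probe sets or adjusted over the list alone; at an unadjusted p under 0.05, 3 were higher and 1 lower. Chgb measured 0.15, Vgf 0.14 (limma adjusted p = 0.0882), Chga 0.12 (0.145), Cpe -0.10 and Scg2 -0.02, which was 0.02 under quantile normalization. Vgf and Chgb were called higher under quantile normalization (limma adjusted p = 0.0165 and 0.0470) and with median centring (0.0320 and 0.0491), and Chgb without no forskolin replicate 2 (0.00435). The median of this list was below 0 and its mean above, and camera did not call it (adjusted p = 0.403). Bdnf lay below the filter, with log2 differences of 0.13 and 0.14 in 2 probe sets.

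Of 20 genes of exocytosis and the synaptic vesicle, Syt4, a synaptotagmin of neuronal and endocrine vesicles, rose 1.71-fold and none fell; the count adjusted over the list alone was also 1. Syt9 measured 0.13, Stx1a -0.10 and Sv2c 0.10 without a call. Camera called the list higher on chip A (adjusted p = 0.0376), against adjusted p = 0.512 with an estimated correlation; it was 0.0642 without forskolin replicate 1 and 0.285 without no forskolin replicate 1. On chip B camera did not call it (0.584), and its median was below 0 and its mean above. Of 18 genes of neurite growth none was called by limma (unadjusted p under 0.05 in 3 higher and 1 lower), and adjusted over the list alone 1 rose; Map1a measured 0.18 (limma adjusted p = 0.0714, but 0.0279 under quantile normalization, 0.0232 with median centring and 0.0462 without forskolin replicate 1), Tubb3 0.12, Map1b 0.11 and Stmn3 -0.10, and camera did not call the list (0.355). None of 16 voltage-gated channel and nicotinic receptor genes was called by limma, also adjusted over the list alone (1 higher at an unadjusted p under 0.05), and Kcnq3 (0.11), Chrna7 (0.09), Cacnb3 (0.09) and Cacnb2 (0.09) had the smallest p. Camera called this list higher (adjusted p = 0.00831) with a median of 0.05 (log2), but adjusted p = 0.408 with an estimated correlation, and 0.139 without no forskolin replicate 1.

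Of 17 circadian clock genes, 4 rose and none fell; adjusted over the list alone, 5 rose. Bhlhe41 and Bhlhe40, repressors that act on the clock, rose 2.42-fold and 1.63-fold on chip A, with 0.34 (log2, not called) for Bhlhe40 on chip B. Per1, a clock repressor that responds to CREB, rose 1.63-fold and Cry2 1.21-fold (limma adjusted p = 0.0346), with an adjusted p of 0.129 for this Cry2 probe set without forskolin replicate 1, 0.0503 by eBayes without a trend and 0.0565 with no filter on dim probe sets. The other Cry2 probe set rose by 0.28 (log2, limma adjusted p = 0.00682). Camera called the list higher on chip A (adjusted p = 6.93e-04), and 0.0342 without the genes shared with the immediate early list, but adjusted p = 0.342 with an estimated correlation. On chip B it was not called (0.106), although it was without forskolin replicate 1 (0.0372).

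Of 36 cell cycle and DNA replication genes, 1 fell and none rose; adjusted over the list alone, 2 fell. Ccnb1, a mitotic cyclin, fell 1.11-fold (limma adjusted p = 0.0441), a call lost without each of the 4 arrays of chip A in turn (0.0604 to 0.187), by eBayes without a trend (0.0998) and with no filter (0.0617). Its other probe set measured -0.03 (0.756). Top2a measured -0.21, Mcm6 -0.15 and Mcm4 -0.15 on their brightest probe sets, none of them called, while the other Top2a probe set fell by 0.18 (log2, limma adjusted p = 0.0440). The brightest ones were called lower with median centring (limma adjusted p = 0.0191, 0.0243 and 0.0421), those of Top2a and Mcm6 also under quantile normalization (0.0455 and 0.0367), Top2a without forskolin replicate 1 (0.0368), and Top2a and Mcm4 without no forskolin replicate 1 (0.00739 and 0.0423). The 3 probe sets of Ccnd1 measured 0.05 to 0.11 without a call. Camera called the list lower on chip A (adjusted p = 9.81e-04, median -0.05), against adjusted p = 0.462 with an estimated correlation, and did not call it on chip B (0.707). Of 15 cell cycle inhibitors and growth arrest genes, 5 rose and 3 fell; adjusted over the list alone, 8 rose and 4 fell. Tob1, an antiproliferative protein, rose 2.17-fold, Gadd45b 1.83-fold and Gas1 1.35-fold, while Gadd45a and Gadd45g fell. The remaining calls, named after their values were seen, were rises in Btg1 (1.16-fold) and Mdm2 (1.13-fold) and a fall in Ccng2 (1.19-fold). Of the 3 tested Mdm2 probe sets only 1 was called, and they ranged from 0.12 to 0.18 (log2). Cdkn1a, also named afterwards, was not called on its brightest probe set. Its other one was called higher, and the 2 measured 0.13 and 0.30. The inhibitor list was called higher by camera (adjusted p = 0.0116), with adjusted p = 0.354 with an estimated correlation, and 0.0642 without forskolin replicate 1.

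Of 18 sterol synthesis and uptake genes, 3 rose and none fell; adjusted over the list alone, 4 rose. Insig1, which holds back sterol synthesis, rose 1.42-fold, Idi1 1.36-fold and Sqle 1.13-fold (limma adjusted p = 0.0383), the last a call lost without each of the 4 arrays in turn (0.0743 to 0.131), by eBayes without a trend (0.0624) and with no filter (0.0519). Cyp51 measured 0.18 (0.0664, but 0.0304 under quantile normalization and 0.0239 with median centring). Sc5d, named after its values were seen, was not called on its brightest probe set. Of its 3 tested probe sets 1 was called lower, and they ranged from -0.22 to 0.11 (log2). The list was called higher by camera (adjusted p = 0.00597), but adjusted p = 0.342 with an estimated correlation. Of 26 genes of the unfolded protein and amino acid stress response, 4 rose and none fell; adjusted over the list alone, 6 rose and 1 fell. Ddit4, an inhibitor of mTOR complex signalling, rose 2.30-fold and Ppp1r15a, which restores translation after stress, 1.66-fold. Chac1 rose 1.23-fold and Atf4 1.17-fold, but the limma adjusted p of Chac1 was 0.0547 without forskolin replicate 1 and 0.0503 without forskolin replicate 2, and that of Atf4 was 0.0688 without forskolin replicate 2. This list, too, was called higher by camera (adjusted p = 0.00597), against adjusted p = 0.342 with an estimated correlation.

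Of 13 heat shock proteins and cochaperones, Bag3 (1.34-fold) and Hspb8 (1.12-fold) rose and none fell; adjusted over the list alone, 4 rose and 1 fell. The limma adjusted p of Hspb8 was 0.0326, and 0.0867, 0.0993 and 0.141 without forskolin replicate 1, forskolin replicate 2 and no forskolin replicate 2. By eBayes without a trend it was 0.0809, and its other probe set measured 0.13 (0.125). Dnajb1 measured 0.23 and Hmox1 0.11 without a call, though Dnajb1 was called higher with median centring (limma adjusted p = 0.0397), without forskolin replicate 2 (0.0380) and without no forskolin replicate 1 (0.00457). Camera did not call the list (adjusted p = 0.138), although it did without forskolin replicate 2 (0.0497). Of 20 genes of glucose metabolism and hypoxia, Vegfa, an angiogenic growth factor, rose 1.35-fold and Egln3, an oxygen-sensing hydroxylase, 1.22-fold; the count adjusted over the list alone was also 2. Pfkfb3 measured 0.10 and Pgam1 -0.06. The median of that list was below 0, its mean was above 0, and camera did not call it (0.289).

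None of 24 oxidative phosphorylation genes and none of 14 ribosomal protein genes was called by limma, over all probe sets or adjusted over the list alone; at an unadjusted p under 0.05, 4 of the first and 1 of the second were lower. Atp5po measured -0.12, Ndufs1 -0.11, Cox5b -0.10 and Ndufa1 -0.09 (log2; limma adjusted p = 0.0928 to 0.204). Camera called the oxidative phosphorylation list lower (adjusted p = 0.0376), with adjusted p = 0.512 with an estimated correlation, 0.194 without forskolin replicate 1, 0.195 without no forskolin replicate 1 and 0.165 under quantile normalization. Among ribosomal proteins Rpl35 measured -0.10, Rps3 -0.09, Rpl5 -0.05 and Rpl6 0.05. With median centring Atp5po (limma adjusted p = 0.0466) and Rpl35 (0.0446) were called lower. Camera did not call the ribosomal protein list (0.0563), although it did without forskolin replicate 1 (0.0436).

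Markers of other cell types were not called by limma, over all probe sets or adjusted over each list alone; at an unadjusted p under 0.05, 1 fibroblast gene was higher and 1 glial gene lower. Among 8 fibroblast genes Col1a1 measured 0.14 (limma adjusted p = 0.125), Col5a2 -0.05, Fbln1 0.05 and Col3a1 0.01, and camera did not call the list (0.330). Among 5 glial genes Cnp measured -0.10, Sox10 0.06, Mbp 0.03 and Gfap -0.02. Among 5 adrenal cortex genes Nr5a1 measured 0.12, Cyp11a1 0.11, Scarb1 0.09 and Cyp21a1 0.07, and among 6 genes of blood and endothelium Tek measured -0.16, Cd68 0.08, Lyz2 0.07 and Aif1 -0.05. The last 3 lists had fewer than 5 tested genes on each chip and were not tested as lists. The adrenal cortex genes had a median of 0.09 (log2) at a median level of 7.42. That exceeds the 0.06, at a level of 7.83, of the channel and nicotinic receptor genes, a list that camera called higher. Whether shifts this small follow brightness was not tested.

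**Figure D3:**
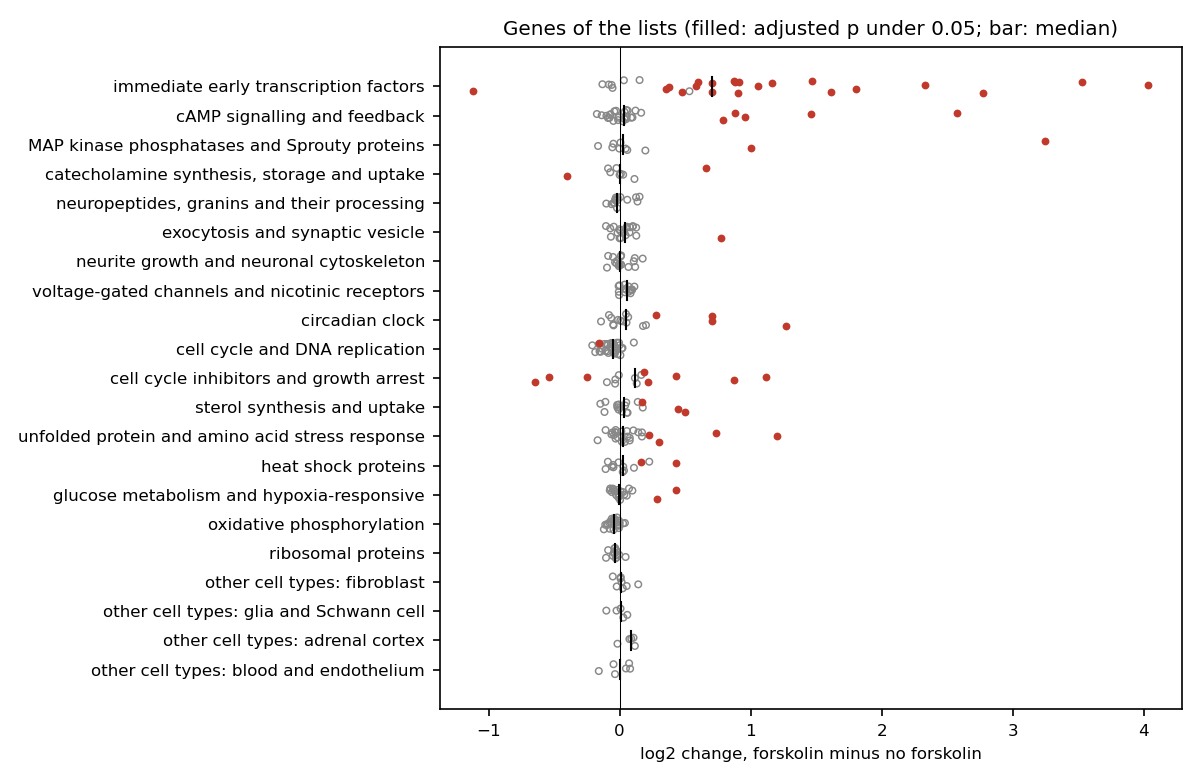
Log2 change (forskolin minus no forskolin) of each tested gene of the 21 lists, through its brightest probe set, with filled red points for adjusted p under 0.05, open grey points for the rest, and a vertical bar at the median of each list (vertical jitter carries no meaning). The immediate early list has a median of 0.70, and the medians of the other lists lie between -0.05 and 0.12.

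Chip B carries many probe sets without a gene symbol, and 8 named genes rose on it. Atoh7, a basic helix-loop-helix factor known from retinal neurons, rose from 5.65 ± 0.25 to 8.62 ± 0.03 (log2, SD, n = 2), 7.80-fold. Its level without forskolin lay below the lowest mean that the filter kept on chip B (6.02), so the size of this rise is uncertain. Crem rose 5.62-fold, Mab21l1 2.31-fold, Pde4d 2.09-fold and Nr4a3 2.06-fold. Zrsr2-ps1 (2.00-fold), Ankrd34b (1.93-fold) and Tp53rkb (1.74-fold) were the other named genes that rose, but the other 2 tested probe sets of Tp53rkb measured 0.19 (limma adjusted p = 0.977) and 0.04 (1). Ddhd1 measured 0.59 (limma adjusted p = 0.0695) and Fosl2 0.67 (0.0885), neither called; both were called under quantile normalization (0.0126 and 0.0344), without no forskolin replicate 1 (0.00815 and 0.0271) and without no forskolin replicate 2 (0.00424 and 0.00383). On chip A Fosl2 rose by 0.58 (log2, limma adjusted p = 0.00113). The limma adjusted p of the 8 genes that rose lay between 1.93e-04 and 0.0320; without forskolin replicate 2 it was 0.0910 for Pde4d, 0.0627 for Zrsr2-ps1 and 0.112 for Tp53rkb, which stood at 0.175 without forskolin replicate 1.

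Among 10693 tested probe sets on chip B, limma called 16 higher and 1 lower, or 0.159%, of which 7 higher and the lower one have no gene symbol here. At an unadjusted p under 0.05, 175 were higher and 356 lower. These 531 are close to the share of 0.05 that would pass with no change at all. Setting replicate 1 against replicate 2 gave 739. The median log2 change of all tested probe sets was -0.026, which leans the same way as the larger number lower. The groups did not overlap in 32.7% of probe sets, close to the 33.3% of chance. Without no forskolin replicate 1 the counts were 37 higher and 57 lower, and without no forskolin replicate 2 they were 41 and 5; without forskolin replicate 2 there were 10 higher, and without forskolin replicate 1 there were 0 lower. Quantile normalization gave 27 higher and 3 lower. Camera called the immediate early list (7 genes, adjusted p = 6.52e-15) and the cyclic AMP list (8 genes, adjusted p = 1.72e-05) higher; each had adjusted p = 0.125 with an estimated correlation.

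Genes with probe sets on both chips allow the measurements to be set side by side. Of 1564 genes tested through different probe sets on the 2 chips, 40 were called on chip A, and 32 of these had the same sign on chip B. All 9 that were called at 1.5-fold or more on chip A had the same sign on chip B. Of these, 4 were also called on chip B, with Crem at 0.88 and 2.49 (log2), Nr4a3 at 3.53 and 1.04, and Pde4d at 0.95 and 1.07. The other 5 were not called there. Mat2a stood at 0.99 and 0.15 (limma adjusted p = 0.977 on chip B), Pi16 at 0.59 and 0.20 (0.977) and Bhlhe40 at 0.70 and 0.34 (0.602). Lpin1 stood at 0.76 and 0.56 (0.229) and B3gnt2 at 0.61 and 0.73 (0.252). Across the 1564 genes the log2 changes correlated at 0.50 (Pearson) and 0.31 (Spearman), and across the 100 probe sets that are on both chips at 0.33 (Pearson). Genes and probe sets are not independent replicates. Across both chips, 108 genes had 2 or more tested probe sets and at least 1 call. In 24 of them all probe sets were called the same way, in 84 some were not called, and in none were calls of opposite direction.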

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

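The alternative without genes shared with the immediate early list was chosen after seeing the data; all others were fixed beforehand. Of 821 values that alternatives gave for the 64 called results on named genes, 787 kept direction and side of the threshold, 34 kept the direction but lost the call, and none reversed; of 740 values for uncalled results, 703 stayed, 31 became calls and 6 reversed. The reversed ones lay near 0 (log2): Scg2 at 0.024 under quantile normalization and -0.058 to 0.021 with an array left out, Lyz2 at -0.0063 to 0.150, Aif1 at -0.108 to 0.015, and Mbp at -0.041 to 0.097. On chip A, the count of higher probe sets moved by over 1.5 times only at a minimum of 1.5-fold (75). Lower probe sets numbered 277 with median centring, 258 at adjusted p under 0.10, 7 at a minimum of 1.5-fold, and 83 to 192 with an array left out (83 and 85 without forskolin replicates 1 and 2). On chip B, 27 were higher and 3 lower under quantile normalization, 0 lower with a pseudocount at the 25th percentile, 3 lower at adjusted p under 0.10, and 10 to 41 higher and 0 to 57 lower with an array left out (37 and 57 without no forskolin replicate 1, 41 and 5 without replicate 2 of that group). Leaving out an array leaves a lone sample that is assumed to vary like the other group. Replicate numbers share no stated origin, and the main fit did not take them as pairs. Deviations of same-numbered arrays correlated at 0.003 on chip A and 0.197 on chip B. A factor shared by same-numbered arrays of chip B is therefore not excluded. With the replicate number as a block, limma called 159 higher and 46 lower on chip A, and 15 higher and 2 lower on chip B; 8 named genes were no longer called, namely Lcat (adjusted p = 0.0647), Egln3 (0.0566), Cry2 (0.148), Ccnb1 (0.113), Sqle (0.0930), Chac1 (0.0532) and Hspb8 (0.0898) on chip A and Tp53rkb (0.0534) on chip B, while Dnajb1 became a call (0.0437). With an estimated correlation every list call of camera was lost. Adjusted p was 0.0998 for the immediate early list, 0.342 for cyclic AMP, MAP kinase phosphatases, clock, sterol and stress response, and 0.354 for cell cycle inhibitors. It was 0.408 for channels, 0.462 for the cell cycle, 0.512 for exocytosis and oxidative phosphorylation, and 0.125 for both lists on chip B. The estimated correlation was -0.004 for the immediate early list, 0.002 for cyclic AMP and -0.053 for sterol on chip A, below the preset 0.01. Higher correlation therefore did not take these calls away. This setting rests its p-values on the few arrays of a chip, so its losses cannot tell whether correlation between genes made the calls. Fry gave 0.344 for exocytosis, 0.167 for channels, 0.141 for the cell cycle and 0.225 for oxidative phosphorylation, and called ribosomal proteins lower (0.0494). The probe set with the smallest p gave 0.118 for exocytosis, 0.109 for sterol and 0.0523 for oxidative phosphorylation, and a filter at the 50th percentile 0.0888 for exocytosis and 0.0872 for oxidative phosphorylation. Quantile normalization gave 0.165 for oxidative phosphorylation and called heat shock proteins higher (0.0378), while ribosomal proteins were called lower with median centring (0.04999) and with no filter (0.0359). With an array left out, adjusted p ranged from 0.00311 to 0.285 for exocytosis, 0.00624 to 0.0642 for cell cycle inhibitors, 0.00630 to 0.195 for oxidative phosphorylation, 0.0436 to 0.194 for ribosomal proteins, 0.0497 to 0.277 for heat shock proteins, 0.00966 to 0.139 for channels and 0.0529 to 0.940 for neurite growth, which turned lower without no forskolin replicate 1. On chip B it was 0.0372 to 0.729 for the clock, 0.262 to 0.700 for the cell cycle and 0.296 to 0.988 for exocytosis, both of which changed direction without a call. The cause of the other shifts was not tested. No background or detection values were used here, so how far dim probe sets lie above background is not known.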

Other observations

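The genes of the first 2 paragraphs and the sets of 6 genes below them were chosen after their values were seen, as were both tests of the spread on chip B, the added checks of brightness and the requirement that a target list hold with each array left out; the other tests were fixed before their results were seen. On chip A, Phox2a, which drives noradrenergic identity, rose 1.33-fold from a high level (12.02, log2), and Gata2 rose 2.55-fold. Isl1 rose 1.17-fold, with 0.04 (log2, not called) on chip B, and Hand2 rose 1.21-fold on 1 probe set while its brighter one measured 0.16 (limma adjusted p = 0.0876). The SoxC factor Sox4 rose on both chip A probe sets (0.56 and 0.59, log2), with 0.36, 0.31 and 0.42 on 3 uncalled probe sets of chip B. The Notch target Hes1 rose 2.09-fold and the Notch ligand Dll1 1.38-fold.

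Among enzymes and their regulators, Mat2a, which makes S-adenosylmethionine, rose 1.99-fold and 2.26-fold on 2 probe sets, with 0.15 (log2, not called) on chip B, and Azin1, which frees ornithine decarboxylase from its antizyme, rose 1.88-fold and 1.78-fold. The transcription coregulator Cited2 rose 1.86-fold and 2.02-fold, the kinase gene Plk2 2.12-fold, the insulin receptor substrate Irs2 1.53-fold, the calcineurin regulator Rcan1 1.42-fold and the stress cytokine Gdf15 1.56-fold. Arrdc3, an arrestin relative of Txnip, fell 1.33-fold. Relabelling each chip's arrays in the other 2 ways that set 2 against 2 gave 0 limma calls each time, against 366 on chip A and 17 on chip B. With 3 splits in all the share cannot fall under 0.05. Each of those splits mixes forskolin and control arrays in both groups, so forskolin changes widen the spread within groups and lower the calls. The 0 calls are therefore no measure of what chance gives. At unadjusted p under 0.05 those splits gave 205 and 120 on chip A against 1934, but 739 and 228 on chip B against 531. The 205 and 739 came from replicate 1 against replicate 2. On chip B the replicate number thus separated more probe sets at that threshold than forskolin did.

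The Id genes and 3 genes of BMP signalling rose on chip A. Id3 rose by 1.92, Id1 by 1.04, Bambi by 0.94, Smad1 by 0.48, Id2 by 0.41 and Bmp2 by 0.39 (log2), while another Id2 probe set measured 0.36 (limma adjusted p = 0.0791). Array scaling is argued against by array medians that differed by at most 0.021 (log2) on chip A, too little for changes of this size. The median of these 6 genes was 0.71 under quantile normalization, which given those medians adds no separate test. A candidate explanation is higher output of BMP target genes: of 18 other BMP targets listed before the test only 5 were tested, their median of 0.10 stood at percentile 99.42 of 10000 random lists matched on brightness, none was called, and the percentile fell to 93.5 without forskolin replicate 1. With so few genes the explanation stays open, as does a direct response of these genes to cyclic AMP, which was not tested.

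Txnip, Klf6, Pik3ip1, Gadd45a, Sesn1 and Ccng2 fell together on chip A, by 0.25 (Ccng2) to 1.51 (Txnip) on the log2 scale, with -0.30 (not called) for Sesn1 on chip B. Array scaling is argued against by the same small difference of array medians, at most 0.021 (log2). The median of the 6 genes was -0.68 under quantile normalization, which again adds no separate test. Lower output of FOXO target genes is a candidate explanation, since several of these genes are known FOXO targets. The 6 genes were chosen after they were seen to fall, however. Irs2 and Ddit4, also known as FOXO targets, rose by 0.62 and 1.20 (log2) on chip A. Of 18 other FOXO targets listed before the test, 11 were tested and lay between -0.09 and 0.10 (log2) with none called. Their median of 0.0013 stood at percentile 79.05 of matched random lists. With an array left out, the median ranged from -0.04 to 0.05 and the percentile from 23.4 (without no forskolin replicate 1) to 99 (without no forskolin replicate 2), so the explanation has no support here but stays open, also because the list leaves out the FOXO targets that were called.

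Chip B called 0.159% of tested probe sets and chip A 3.30%. Larger spread on chip B may be part of the cause, since the 100 shared probe sets had a within-group SD 2.12 times that on chip A. As the whole cause it is argued against by changes of at least 2-fold, which noise should not remove. Their share was 0.266 times that on chip A (95% interval 0.133 to 0.533, 10 against 39 probe sets). The interval takes probe sets as independent, although some belong to the same gene, such as Dusp1 on chip A and Crem on chip B. It is therefore likely too narrow, and the argument is weaker than it makes it look. For the chip B probe sets that could be matched, dimness as the whole cause is argued against by chip A probe sets of matched brightness. Of these, 3.16% were called (2.81 to 3.55 over 1000 draws, covering 77.6% of chip B probe sets). The chips were scaled separately, so chip B levels were raised by 0.37 (log2), the offset of the shared probe sets. Without that offset the share was 3.08%, covering 62.8%. The filter kept probe sets from 7.02 on chip A and 6.02 on chip B (log2 of the linear mean). The dimmest chip B probe sets thus had no match, and for them the check cannot tell. Within chip A 2.66% were called in the dimmest of 5 equal bins of tested probe sets. A difference in which genes the chips carry stays open, and no biological explanation was tested.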
